A study of Mus musculus with 9 samples.

How the data were processed

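Total RNA was extracted from the tissue with a column kit, and libraries were made and sequenced on a DNBseq instrument, per the labels' protocols. The 9 libraries fell into 3 groups of 3, taken from the treatment label of each sample. The deposited files held 1 TPM value per gene and library, rounded to 2 decimals, per the file headers and the values. The aligner HISAT and the genome builds GRCm38.p6 and mm10 were named in the submitters' processing notes without versions, while the quantification tool, gene annotation and filters were not given in the sources used here. TPM divides by gene length and by the library's own total, so the totals of the libraries were equal within rounding, at most 0.74 TPM off, and a rise of some genes lowers the values of the rest. TPM keeps no depth, so no counting interval was given and no count model was used.

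Each file held the same gene symbols. Plin2 had 2 entries, which were kept apart, 1 symbol had been turned into a date, 0 entries were of mitochondrially encoded genes, and 239 were at 0 in every library. No 2 libraries held the same values: at most 0.42% of tested genes had equal TPM in 2 libraries of a group. Gene positions were taken from a RefSeq table of GRCm38.p6, the build the notes name, and count from 1.

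Values were analysed as log2(TPM + 1), and log2 fold changes are on that scale, which understates the change of genes with low TPM. Genes with 1 TPM or more in at least 3 libraries, 13829 in all, were tested with limma 3.58.1 in R 4.3.3 (a moderated linear model with an intensity trend), with all 9 libraries in one fit so that the groups shared an estimate of spread. P-values were adjusted by the Benjamini-Hochberg method within each comparison, at a threshold of 0.05. The 27 gene lists were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. camera compares the members of a list with all other tested genes. A list called higher or lower therefore lies above or below those genes, not 0. The median log2 fold change of all tested genes was -0.10 for ThTC against GFP-TC, -0.032 for ThTC against sECM only and 0.077 for GFP-TC against sECM only. The directional fry test called 0 lists in each comparison, and its test for changes in either direction gave neutrophils adjusted p = 0.00483 for ThTC and 0.00119 for GFP-TC against sECM only. Retnlg had the smallest p of that list in both, and camera called the list in neither, so the value is not a result about neutrophil genes in general. Ifnb1 and Csf2 lay below the filter and were compared by exact two-sided permutation tests. Figures were drawn in Python 3.11.15 with matplotlib 3.10.9.

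The tests, lists, first alternatives and the rule for named genes were fixed before the data were examined. The rule took, per comparison, up to 10 genes per direction with the largest change among genes that were called, did not overlap between groups, averaged 5 TPM or more and had an established symbol. If none passed, it took the 5 with the smallest p. It also took the 3 members with the smallest p of every called list, and 10 fixed genes. Since 0 genes were called, the second clause applied; keeping the conditions on overlap, level and symbol in it was a reading settled after that was known. Genes named outside the rule are Tyrobp, Trem2, Gzmf, Selenop, Cyba, Postn and Sfrp4 of the blocked fit, the tissue markers Snap25, Mbp, Ttr and Hbb-bs, S100a9 and Sox9, the plotted genes Adamdec1, Alox15 and Mgl2, and Rnase2a, Retnla and the marker list members of the closing part, which were chosen after their values were seen or for a later test.

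Same-numbered libraries were checked for pairing by correlating their deviations from the group means over tested genes. GFP-TC and ThTC libraries correlated at 0.74, 0.12 and 0.87 for numbers 1, 2 and 3, all over 0.1, so these numbers were treated as pairs. The labels do not say what the numbers stand for. Libraries of different numbers correlated too: GFP-TC 1 with ThTC 2 at 0.38, and sECM only 1 with GFP-TC 3 and ThTC 3 at 0.61 and 0.56. The pairing is therefore an assumption that these values do not establish, and every result by pairs rests on it. The sECM only libraries correlated at -0.53, -0.14 and -0.19 with GFP-TC and at -0.55, 0.28 and -0.205 with ThTC, and were not treated as paired.

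The steps were tested on simulated data for the comparison of ThTC with GFP-TC, with the real means and spreads of the 13829 genes and 200 changed genes in each of 20 draws. With the libraries' own gene correlations, 19.3% of genes changed 1.5-fold, 53.5% of those changed 2-fold and 83.2% of those changed 4-fold were called, with a median of 0 false calls. In 100 sets with no changed gene, limma with equal weights called genes in 3 sets. The preset list test called a median of 11.5 lists and up to 22, and the test with an estimated correlation called 0 in all 100 sets. In 100 further sets, where GFP-TC and ThTC libraries of the same number shared deviations as in the data, the preset list test called a median of 12 lists and up to 18.

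The alternatives fixed beforehand were other pseudocounts, filters and scalings, the 6 libraries of a comparison alone, a replicate block, sample quality weights, robust moderation, a minimum fold of 2, an estimated correlation, and each library left out in turn. The alternatives added after seeing the data were a brain tissue covariate (the mean log2 level of the neuron and oligodendrocyte lists), leaving out GFP-TC 3 and ThTC 3 together, leaving out GFP-TC 1 and ThTC 1 together, the replicate block within the 6 libraries, and gene-by-gene sample quality weights, the last because the default weights stopped with a warning before reaching their tolerance.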

Results

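Bulk RNA sequencing was carried out on tumour tissue taken from mouse brains 5 days after tumour resection. The tumours came from CT2A, a mouse glioma cell line. Each of 3 treatment groups held 3 libraries, named here by group and replicate number. The first group received sECM only, the second GFP-TC control cells, and the third ThTC, cells that secrete interferon-beta (IFNβ) and GM-CSF. Every file gave TPM, a transcript abundance corrected for gene length and library total, for the same genes, and 13829 genes were tested. TPM adds up to the same total in each library by construction, so the read depth behind each value is unknown beyond the 4.47 Gb of bases per sample that the labels state. The labels do not say that the libraries of a group came from separate animals, so the p-values measure only the spread between these libraries.

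The mouse genes of both secreted factors had low values in every library. The labels do not give the sequence from which the cells express the factors, and a sequence that differs from the mouse transcripts would be missed by these values. Ifnb1 (chromosome 4, 88522025 to 88522794, GRCm38.p6), which encodes IFNβ, lay between 0 and 0.33 TPM, and Csf2 (chromosome 11, 54247270 to 54249899), which encodes GM-CSF, lay between 0 and 0.34 TPM. Mean Ifnb1 was 0.15 ± 0.01 TPM with ThTC and 0.213 ± 0.0751 TPM with GFP-TC (SD, n = 3; exact permutation p = 0.1, two-sided, the smallest that 3 against 3 allows), and all 3 ThTC libraries lay below all 3 GFP-TC libraries. With sECM only it was 0.16 ± 0.165 TPM (exact permutation p = 1 against ThTC). Mean Csf2 was 0.20 ± 0.121 TPM with ThTC, 0.0467 ± 0.0808 TPM with GFP-TC and 0.147 ± 0.168 TPM with sECM only (SD, n = 3; exact permutation p = 0.3 and 0.5 for ThTC against each). The receptor genes were at 40.6 to 51.9 TPM for Ifnar1, 86.3 to 116 TPM for Ifnar2, 19.96 to 61.0 TPM for Csf2ra and 6.96 to 28.7 TPM for Csf2rb over the 9 libraries, and none differed between groups in limma after adjustment.

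The libraries differed widely in the levels of genes of brain cell types, within groups too. The first principal component took 66.9% of the variance, with ThTC 3 and GFP-TC 3 at one end (-65.15 and -53.7) and GFP-TC 1 at the other (54.7). Snap25, a synaptic gene of neurons, ran from 18.5 TPM in GFP-TC 1 to 414 TPM in ThTC 3, and Mbp, a myelin gene of oligodendrocytes, from 68.1 TPM in ThTC 1 to 1232 TPM in ThTC 3. GFP-TC 3 was the other library rich in brain RNA, with 314 TPM of Snap25. GFP-TC 1 had both the lowest neuron score (-1.78, the mean log2 level of the list centred per gene) and the lowest T cell score (-1.46) of the 9 libraries.

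**Figure D1:**
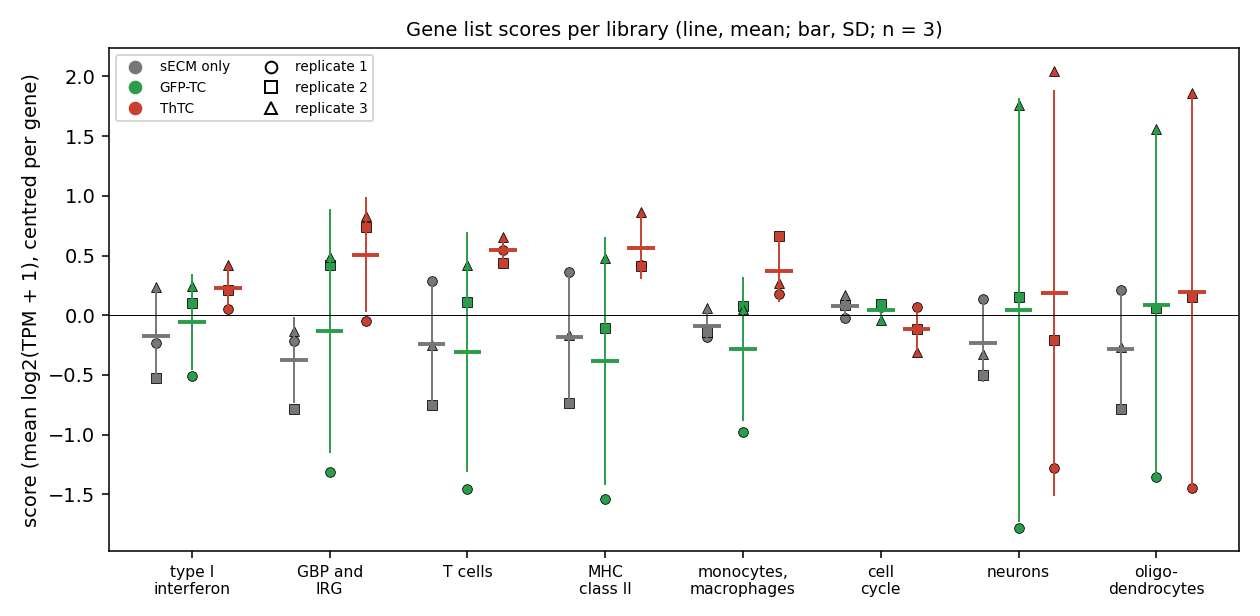
Scores of 8 gene lists in each library, as the mean of log2(TPM + 1) over the list's tested genes after centring each gene, by treatment group; points are libraries, horizontal lines group means and vertical bars SD (n = 3). GFP-TC 1 lies at -1.46 for T cells and -1.78 for neurons, while ThTC 3 reaches 2.05 for neurons.

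The comparison of ThTC with GFP-TC asked what the secreted factors add to the control cells. Most members of the immune gene lists had higher means with ThTC. Ifi27l2a, an interferon-inducible gene (chromosome 12, 103433873 to 103443680), was at 272.8 ± 22.4 TPM with ThTC and 137.0 ± 13.2 TPM with GFP-TC (SD, n = 3), a 1.99-fold difference. Pdgfrb, a growth factor receptor gene of pericytes and fibroblasts (chromosome 18, 61045127 to 61085067), had a lower mean with ThTC, at 32.9 ± 1.55 TPM against 56.3 ± 7.67 TPM, as did Notch3, a Notch receptor gene of pericytes and smooth muscle (chromosome 17, 32120820 to 32166896), at 5.11 ± 0.093 TPM against 9.30 ± 0.74 TPM. The groups did not overlap for any of these 3 genes, which was a condition for naming them. None passed the adjustment over all genes (limma, adjusted p = 0.32 each). Ifi27l2a did pass in limma with a replicate block in the 6 libraries (adjusted p = 0.022), a fit chosen after the data had been seen.

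No gene was called in this comparison with limma at an adjusted p of 0.05. At an unadjusted p under 0.05 there were 2065 genes, 281 higher and 1784 lower with ThTC, where 691 would be expected of independent genes. In 100 simulated unchanged sets with the gene correlations seen here the median was 140.5 and the highest 6334, with 2065 or more in 10 sets (9 when pairs shared their deviations). The count was 770 without GFP-TC 2, 779 without ThTC 2, 3389 with the brain tissue covariate and 1289 after median-of-ratios scaling, where 774 were higher and 515 lower. With a minimum fold of 2 it was 43, with 29 higher and 14 lower. The groups did not overlap for 304 higher and 2333 lower genes, together 19.1% of those tested, where independent genes would give 10%. The lower genes made up 88.5% of these as deposited and 50.2% after scaling by median-of-ratios factors (a scaling that centres the genes), which moved the median of all genes by 0.12 on the log2 scale. Of genes with an established symbol, an average of 5 TPM or more and no overlap, those with the smallest p among higher ones, besides Ifi27l2a, were Ptpn18 (41.4 ± 3.27 against 23.7 ± 2.66 TPM), Tspo (347.2 ± 22.6 against 240.2 ± 17.5 TPM), Insl6 and Ostf1, and among lower ones, besides Notch3 and Pdgfrb, Gab1 (20.5 ± 1.48 against 30.6 ± 2.28 TPM), Scgb3a1 and Repin1, each at an adjusted p of 0.32 and so not passing.

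Of the 27 gene lists, camera with its preset correlation of 0.01 called 16 higher and 1 lower with ThTC, and 0 with an estimated correlation. The type I interferon list had 37 of 43 tested members higher, with a median log2 fold change of 0.28, and Ifi27l2a passed when adjusted over the list alone while 0 members were called over all genes. The lymphocyte lists had larger medians: 0.87 for T cells, where 19 of 20 members were higher, and 0.83 for cytotoxic T and NK cells, where all 19 tested members were higher. Without GFP-TC 1 these medians were 0.22 and 0.26, and that of type I interferon genes 0.070. The scores of pairs 1, 2 and 3 differed by 2.0, 0.33 and 0.23 for T cells and by 1.66, 0.53 and 0.24 for cytotoxic cells. In these lists Cd3d, a subunit of the T cell receptor complex, was at 7.91 ± 0.67 TPM against 2.84 ± 1.95 TPM, and the granule protease gene Gzma at 52.7 ± 14.5 TPM against 19.1 ± 12.2 TPM. Gzmk, another granule protease gene, passed when adjusted over the list alone, at 2.19 ± 0.39 TPM against 0.43 ± 0.27 TPM. These calls were lost with an estimated correlation (adjusted p = 0.57 for each of these 3 lists).

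Antigen presentation and myeloid lists were called in the same direction. All 11 tested MHC class II genes were higher (median log2 fold change 0.91), with H2-Aa at 721.7 ± 137.1 TPM against 320.3 ± 237.5 TPM, and 17 of 22 MHC class I genes were higher (median 0.26), with Psmb9, an immunoproteasome subunit, at 378.4 ± 53.5 TPM against 230.6 ± 41.4 TPM. A further list held GBP genes, IRG genes and other interferon-gamma-inducible genes such as Cxcl9 and Cd274, and is called GBP and IRG genes for short. All 25 tested members had higher means (median 0.61) and all 25 overlapped between groups, with the chemokine gene Cxcl9 at 104.2 ± 37.6 TPM against 52.5 ± 39.8 TPM. All 19 monocyte and macrophage genes were higher (median 0.60), among them Lyz2 at 1036 ± 416 TPM against 498.2 ± 108.9 TPM. With an estimated correlation these 4 lists had an adjusted p of 0.57. The immune checkpoint list (12 of 13 members higher, median 0.70) included Pdcd1, which encodes PD-1, at 10.2 ± 2.19 TPM against 3.93 ± 2.96 TPM, and Cd274, which encodes its ligand PD-L1, at 46.8 ± 14.98 TPM against 37.2 ± 21.8 TPM (adjusted p = 0.57 with an estimated correlation). Without GFP-TC 1 these 5 lists stayed called, with medians of 0.41 for MHC class II, 0.033 for MHC class I, -0.041 for GBP and IRG genes, 0.25 for monocytes and macrophages and 0.034 for checkpoints.

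The remaining called lists had smaller medians or mixed members. Regulatory T cells (median log2 fold change 0.56), microglia (0.45), neutrophils (0.31), GM-CSF receptor and STAT5-responsive genes (0.22), dendritic cells (0.21), chemokines (0.14), cell death and p53 targets (0.10) and inflammatory cytokines (0.04) were called higher. They had adjusted p = 0.57 to 0.62 with an estimated correlation, and neutrophils and inflammatory cytokines lost their calls after median-of-ratios or quantile scaling. Without GFP-TC 1 all 8 lost their calls, and the medians of GM-CSF genes (-0.17), dendritic cells (-0.15), chemokines (-0.15), inflammatory cytokines (-0.16) and cell death (-0.0091) were negative. Without ThTC 3, microglia (0.091), chemokines (-0.21) and inflammatory cytokines (-0.082) lost their calls, as did neutrophils (0.11) and cell death (0.068) without ThTC 2. The cell death call ended in 12 of 24 refits and that of inflammatory cytokines in 8. Among cell death genes the 3 members with the smallest p, Mdm2, Trp53 and Bcl2l11, all had lower means with ThTC. Cxcl10 was at 446.7 ± 138.4 TPM against 416.6 ± 129.0 TPM and Cd8a at 13.4 ± 1.63 TPM against 8.65 ± 7.09 TPM, and both overlapped. The cell cycle list was called lower, with 26 of 30 members lower and a median of -0.17 (adjusted p = 0.70 with an estimated correlation), and its call ended in 10 of 24 refits. Among them were median-of-ratios scaling (median -0.04), quantile scaling (-0.11), a mean TPM of 5 or more (-0.17), both kinds of sample weights (-0.20 and -0.16) and the brain tissue covariate (-0.16). The others included leaving out GFP-TC 1 (-0.16) and leaving out ThTC 3 (-0.070), where the test pointed higher. Mki67, a proliferation marker, was at 40.9 ± 7.09 TPM against 52.0 ± 5.21 TPM. Extracellular matrix and fibroblasts (median -0.21), red blood cells (-1.15), oligodendrocytes (0.09), neurons (0.11), astrocytes (0.13), endothelial cells (-0.01), B and plasma cells (0.04), hypoxia and glycolysis (0.02), skeletal muscle (0.03) and choroid plexus (-0.40) were not called. Some of these were called with a library left out: neurons higher without GFP-TC 3, ThTC 1 or ThTC 2 (medians 1.001, 0.84 and 0.31), and oligodendrocytes higher without GFP-TC 3 or ThTC 1 (0.90 and 0.99) and just so without sECM only 3 (adjusted p = 0.04995). Red blood cells were called lower without GFP-TC 3 or ThTC 2 (-1.95 and -1.54) and extracellular matrix lower without ThTC 2 (-0.32). Hypoxia was called higher without GFP-TC 1, GFP-TC 2 or ThTC 3 (0.064, 0.078 and 0.10), and endothelial cells without GFP-TC 3 or ThTC 1 (0.15 and 0.24). Red blood cells were also called lower with median-of-ratios or quantile scaling (-1.05 and -1.11). The median of endothelial cells and the means of hypoxia and skeletal muscle (-0.02 and -0.13) were negative where the test pointed higher, and the medians of endothelial cells and of hypoxia changed sign with the scaling. Pdgfrb alone in the extracellular matrix list passed when adjusted over that list alone.

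**Figure D2:**
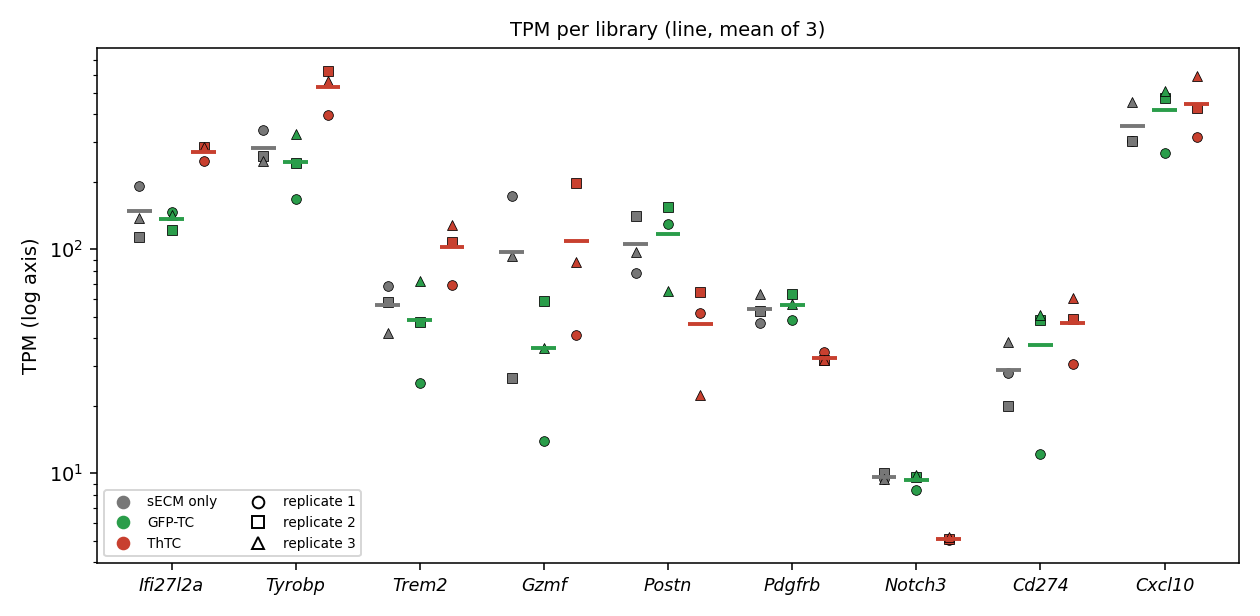
TPM of 9 genes in each library on a log axis, by treatment group; points are libraries and horizontal lines group means (n = 3). Ifi27l2a averages 272.8 TPM with ThTC and 137.0 TPM with GFP-TC, and Pdgfrb 32.9 and 56.3 TPM, with no overlap, whereas Cxcl10 overlaps between the groups.

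The immune list calls carried 2 limits. Without GFP-TC 1, 8 of the 16 higher lists stayed called and the median of the 16 medians was 0.034 instead of 0.38 (13 stayed called without ThTC 3, 14 or more without any other library), while without GFP-TC 1 and its pair ThTC 1 together 11 stayed called with a median of 0.17. In 100 simulated sets of 9 unchanged libraries with the gene correlations seen here the same list test called a median of 11.5 lists, with 17 or more in 22 sets (a median of 12, and 22 sets, when the simulated pairs shared their deviations). Of the 16 list scores, 9 were higher with ThTC in 3 of 3 pairs, and 15 differed most in pair 1, where the median difference was 0.79 against 0.17 and 0.20 in pairs 2 and 3. These counts are no separate support, since the lists were called on these same libraries. Some lists also share members, such as Cxcl9 in the chemokine and interferon-gamma-inducible lists, so they are not independent. Equal weighting mattered too, since sample quality weights called 5866 genes, but such weights also called genes in 54 of 100 simulated unchanged sets. GFP-TC and ThTC libraries of numbers 1 and 3 deviated together, and those of number 2 little. With the replicate number as a block in the 6 libraries, a fit chosen after the data had been seen, limma called 8 genes. It called 0 with a block in all 9 libraries. In the 6-library fit Tyrobp and Trem2, which encode a receptor pair of macrophages and microglia, were higher with ThTC, at 528 ± 115 against 246 ± 79.6 TPM and 102 ± 30.0 against 48.3 ± 23.4 TPM (adjusted p = 0.022 each, and 0.32 without the block). Gzmf, a granule protease gene, was at 109 ± 80.2 against 36.2 ± 22.3 TPM (adjusted p = 0.0048, and 0.39 without the block), and Ifi27l2a, Selenop and Cyba were also higher. Postn, a matrix protein gene, was lower at 46.2 ± 21.5 against 116.5 ± 46.4 TPM (adjusted p = 0.0048, and 0.32 without the block), as was Sfrp4, a gene of Wnt signalling. Each of the 8 genes differed in the same direction in 3 of 3 pairs. That adds no support, since the blocked fit calls genes whose pair differences agree. The blocked fit called 21 lists, adding neurons, astrocytes and oligodendrocytes as higher and red blood cells as lower, and 0 lists with an estimated correlation (smallest adjusted p = 0.44).

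The comparison of ThTC with sECM only covered the whole treatment. Ifi27l2a had a higher mean with ThTC, 272.8 ± 22.4 against 148.1 ± 40.1 TPM, and Ms4a6b was at 51.3 ± 11.7 against 24.4 ± 5.90 TPM (SD, n = 3). Retnlg, a resistin-like gene known from neutrophils (chromosome 16, 48872608 to 48874498), was at 0.97 ± 0.51 TPM against 16.2 ± 7.64 TPM. Hes1, a target of Notch signalling, was at 92.8 ± 10.4 against 152.5 ± 5.32 TPM, and Notch3 itself at 5.11 ± 0.093 against 9.64 ± 0.37 TPM. These groups did not overlap, which was a condition for naming the genes. limma gave adjusted p values of 0.27 for Retnlg and 0.69 for the others, so none passed.

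limma called 0 genes, with 954 at an unadjusted p under 0.05 (213 higher, 741 lower). That number was 332 without ThTC 2, 529 without ThTC 3, 1594 without ThTC 1, 528 without sECM only 2 and 394 without sECM only 3. The groups did not overlap for 695 higher and 1676 lower genes, 17.1% of those tested, where independent genes would give 10%; lower genes made up 70.7% of these as deposited and 51.4% after median-of-ratios scaling. Sample quality weights called 2582 genes, but their fit stopped before reaching its tolerance, and gene-by-gene weights called 0. Under the same conditions of symbol, level and overlap, Ptpn18, Tspo and Insl6 were the other higher genes, and Cdh15 and Scgb3a1 the other lower genes, with the smallest p.

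camera with its preset correlation called 12 lists higher and 2 lower, and 0 with an estimated correlation (adjusted p = 0.63 for all 14). All 43 tested type I interferon genes were higher with ThTC (median log2 fold change 0.42), among them Xaf1 at 88.3 ± 8.09 against 55.6 ± 11.5 TPM and Bst2, an antiviral membrane protein gene, at 1448 ± 176 against 1094 ± 184.5 TPM. All 25 GBP and IRG genes were higher (median 0.82), with Gbp2b at 4.62 ± 2.57 against 0.85 ± 0.46 TPM. All 19 cytotoxic T and NK cell genes were higher (median 0.70), including Ifng, which encodes interferon-gamma, at 5.00 ± 0.99 against 2.67 ± 0.60 TPM. T cells (median 0.81), MHC class I (0.36), MHC class II (0.76), monocytes and macrophages (0.65), microglia (0.48), immune checkpoints (0.58), regulatory T cells (0.61), oligodendrocytes (0.44) and inflammatory cytokines (0.14) were also called higher. Oligodendrocytes lost the call without ThTC 3 (-0.40) or sECM only 2 (0.16), regulatory T cells without ThTC 1 (0.44) or sECM only 2 (0.35), and checkpoints without sECM only 2 (0.35). Inflammatory cytokines lost it in 7 of 24 refits (-0.023 without sECM only 2). All 15 neuron genes were higher as well (median 0.41), and that list was not called, while the neuron score ran from -1.28 in ThTC 1 to 2.05 in ThTC 3. In the checkpoint list Pdcd1lg2, which encodes the PD-1 ligand PD-L2, went the other way, at 1.65 ± 0.13 against 4.47 ± 2.37 TPM.

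The cell cycle list was called lower, with 28 of 30 members lower (median -0.23), and so was the extracellular matrix and fibroblast list, with 14 of 23 members lower (median -0.17). Col6a1 was at 272.8 ± 33.8 against 416.4 ± 67.9 TPM and Fap, a marker of activated fibroblasts, at 13.6 ± 3.95 against 23.9 ± 3.20 TPM, and 3 members passed when adjusted over this list alone, as did Ifi27l2a in the type I interferon list and, in lists that were not called, Retnlg (lower) and S100a9 (higher) among neutrophils and Sox9 (lower) among astrocytes. Both lower calls ended without ThTC 3, the library with the most brain RNA (medians -0.12 and -0.18), and the second also without ThTC 1 (-0.13), without sECM only 2 (-0.17), at a mean TPM of 5 or more (-0.20), with the brain tissue covariate (-0.21) and with both kinds of sample weights (-0.068 and -0.11), where the test pointed higher. Without sECM only 2, 9 lists were called instead of 14. In 42 of the 100 simulated unchanged sets, made for the comparison of ThTC with GFP-TC, 14 or more lists were called.

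The comparison of GFP-TC with sECM only gave the effect of control cells. Retnlg was at 0.56 ± 0.19 TPM against 16.2 ± 7.64 TPM, Ear2, an eosinophil-associated ribonuclease gene, at 0.54 ± 0.38 against 15.9 ± 12.1 TPM, the chemokine gene Ccl24 at 0.92 ± 1.20 against 27.7 ± 18.6 TPM, and Mrc1, the macrophage mannose receptor gene, at 3.90 ± 1.64 against 13.2 ± 5.02 TPM (SD, n = 3). The groups did not overlap for these genes, which the rule for genes with the smallest p required. limma gave an adjusted p of 0.13 for Retnlg and 0.997 for the others, so none passed. With the replicate number as a block in all 9 libraries Retnlg alone was called (adjusted p = 0.0497, within a range of 0.0173 to 1 over the alternatives), although the sECM only numbers were not paired with the others.

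**Figure D3:**
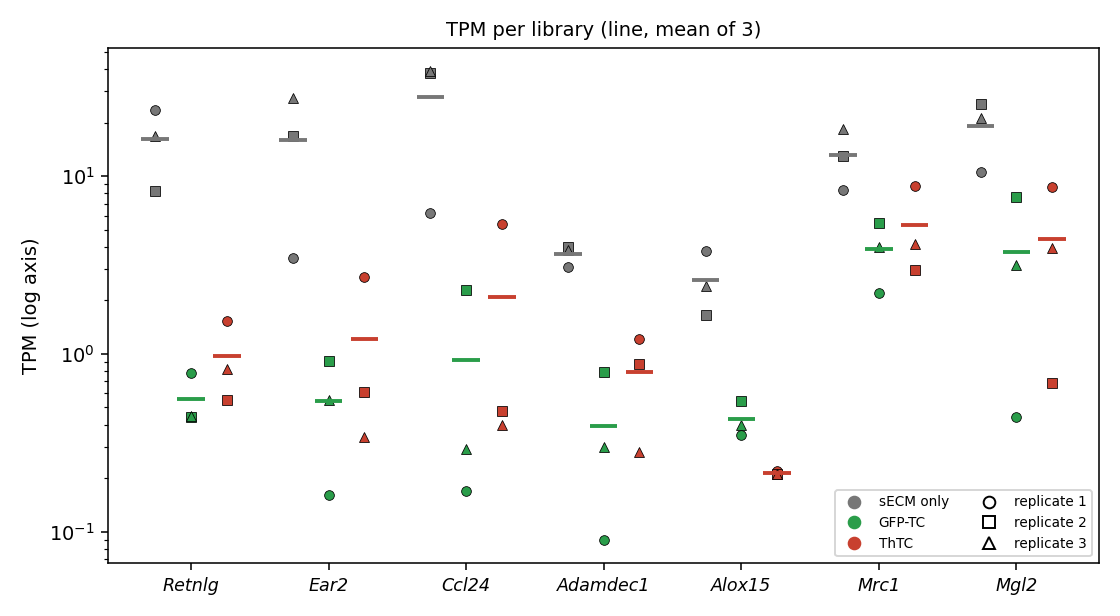
TPM of 7 genes in each library on a log axis, by treatment group; points are libraries and horizontal lines group means (n = 3). Retnlg lies between 8.28 and 23.5 TPM with sECM only and between 0.44 and 1.53 TPM in the 6 libraries with cells.

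limma called 0 genes, and 129 genes had an unadjusted p under 0.05 (69 higher, 60 lower), fewer than the 691 expected of independent genes; the number was 1314 without GFP-TC 1 and 80 without sECM only 1. The groups did not overlap for 436 higher and 149 lower genes, 4.23% of those tested, where independent genes would give 10%; lower genes made up 25.5% of these as deposited and 55.5% after median-of-ratios scaling. Under the same conditions the higher genes with the smallest p were Arhgef28, Wdyhv1, Cdh10, Zfp566 and Aarsd1, the first of them at 11.04 ± 1.32 against 7.51 ± 0.60 TPM, and Hist1h2ao was among the lower ones; none passed.

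camera with its preset correlation called 10 lists lower and 1 higher, and 0 with an estimated correlation (smallest adjusted p = 0.80). In the list of GM-CSF receptor and STAT5-responsive genes 12 of 16 members were lower (median log2 fold change -0.18), and Ccl24 and Ccl17 passed when adjusted over the list alone, the latter at 1.63 ± 0.53 against 6.91 ± 3.12 TPM. Both are chemokine genes. Arg1, the arginase gene of the macrophage list, was at 40.7 ± 41.2 against 151.3 ± 64.9 TPM with overlapping groups. Hypoxia and glycolysis (median -0.13), cell cycle (-0.05), B and plasma cells (-0.18), cytotoxic T and NK cells (-0.08), MHC class II (-0.19), immune checkpoints (-0.003) and skeletal muscle (-0.14) were also called lower. The skeletal muscle call ended in 16 of 23 refits, among them both scalings (-0.19 and -0.20) and no filter (0.0087). Monocytes and macrophages (median 0.06) and dendritic cells (median 0.01) were called lower although their medians lay above 0. camera compares a list with the other genes, and the median of all tested genes was 0.077 here. Both list medians lay below 0 after median-of-ratios or quantile scaling. The first call ended with both scalings and the second with median-of-ratios scaling, and they ended in 9 and 8 of 24 refits. The sign of the median differed from that of the test for 11 of the 27 lists and that of the mean for 7. Choroid plexus and ependyma was called higher (median 0.81, 7 of 7 members higher), but not without GFP-TC 1 or without sECM only 3 (medians 0.82 and 0.69). Without GFP-TC 1, 5 lists were called, of which GBP and IRG genes (median 0.85, against 0.26 with all libraries), type I interferon (0.35, against 0.11) and T cells (0.47, against -0.041) were called higher. The first 2 were also called higher with both kinds of sample weights and without GFP-TC 1 and ThTC 1. Type I interferon was instead called lower without sECM only 2 (median -0.050, camera adjusted p = 0.0017), and the T cell median was -0.31 without GFP-TC 3. Without GFP-TC 1 the tests of MHC class II (median 0.36), cytotoxic cells (0.40), checkpoints (0.38), dendritic cells (0.27) and monocytes and macrophages (0.28) pointed higher. GM-CSF genes (0.16) and B and plasma cells (0.17) lost their calls there with medians above 0, and with both kinds of sample weights too (0.17 and 0.14, and 0.037 and 0.053). Without GFP-TC 3 the test of hypoxia pointed higher (0.049) and the cell cycle call ended (-0.0068), and without sECM only 1 the test of cytotoxic cells pointed higher (0.024). The lists called numbered 4 without sECM only 1 and 5 after median-of-ratios scaling. In 56 of the 100 simulated unchanged sets, made for the comparison of ThTC with GFP-TC, 11 or more lists were called.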

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

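The alternatives with the brain tissue covariate, without GFP-TC 3 and ThTC 3 together, without GFP-TC 1 and ThTC 1 together, with the replicate block in 6 libraries, and with gene-by-gene weights were chosen after seeing the data. The count of 0 called genes held in 13 of 16 alternatives for ThTC against GFP-TC, and in 14 of 16 for each of the comparisons with sECM only. For ThTC against GFP-TC, sample quality weights called 5866 genes, gene-by-gene weights 1245, and the block in 6 libraries 8. For ThTC against sECM only, sample quality weights called 2582 genes, gene-by-gene weights 0 and the brain covariate 2 (Retnlg and Hes1). For GFP-TC against sECM only, the replicate block and the brain covariate each called 1, Retnlg. The default weights gave ThTC 2 a weight of 8.61 and GFP-TC 1 one of 0.22; in simulated unchanged sets they called genes in 54 of 100 and gene-by-gene weights in 33 of 100, so such calls also arose without a difference.

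Gene list counts fell from 17, 14 and 11 to 0 with an estimated correlation in all 3 comparisons. Gene-by-gene weights called 10 lists for ThTC against GFP-TC. For GFP-TC against sECM only, 7 lists were called at a mean TPM of 5 or more, 5 with median-of-ratios scaling, 4 with each kind of sample weights, 5 without GFP-TC 1 and ThTC 1, and 17 without GFP-TC 3 and ThTC 3. With each library left out in turn, genes called ranged from 0 to 0, 0 to 1 and 0 to 1 (Rnase2a without sECM only 1, Retnlg without sECM only 2), and lists from 9 to 20, 9 to 20 and 4 to 16, for ThTC against GFP-TC, ThTC against sECM only and GFP-TC against sECM only. The lowest counts came without GFP-TC 1, sECM only 2 and sECM only 1.

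Lists whose test changed direction are given by their median log2 fold change. For ThTC against GFP-TC this was cell cycle without ThTC 3 (-0.070; range over left-out libraries -0.259 to -0.070). For ThTC against sECM only it was extracellular matrix with sample weights (-0.068) and gene-by-gene weights (-0.11). For GFP-TC against sECM only it was, without GFP-TC 1, MHC class II (range -0.533 to 0.36), T cells (-0.307 to 0.47), cytotoxic cells (-0.34 to 0.40), checkpoints (-0.48 to 0.38), dendritic cells (-0.181 to 0.27) and monocytes and macrophages (-0.148 to 0.28), each range over left-out libraries with its lowest value without GFP-TC 3 and its highest without GFP-TC 1. Without GFP-TC 1 and ThTC 1 it was again MHC class II (0.36), cytotoxic cells (0.40), checkpoints (0.38), dendritic cells (0.27) and monocytes and macrophages (0.28), and neurons (1.19; range over left-out libraries -0.648 to 1.189). It was also cytotoxic cells without sECM only 1 (0.024), type I interferon without sECM only 2 (range -0.050 to 0.36), hypoxia without GFP-TC 3 (range -0.227 to 0.049) and, without GFP-TC 3 and ThTC 3, hypoxia (0.049), microglia (-0.25) and oligodendrocytes (-0.47). The cause was not tested. Of 1920 refits of single lists, 1594 kept their side of the threshold, 169 lost a call and 136 gained one, and of 4346 refits of named genes 4237 kept theirs and 109 gained a call; 116 and 61 of those that kept theirs changed sign with no call on either side. Robust moderation and the minimum fold have no list test, the covariate fit left 25 lists to test, and the filter at 5 TPM 21. The replicate block in 9 libraries left 0 genes called in both comparisons of ThTC, and 17, 17 and 11 lists. Among the 9 libraries, 4 correlated best with a library of their own number outside their group. Read depth is unknown, so its limits could not be assessed.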

Other observations

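The tests of brain tissue, of GFP-TC 1, of neutrophils and of the scaling, the added contrast and the correlations below were chosen after the results they bear on had been seen. Genes of other tissues varied widely between libraries of one group. Ttr, the transthyretin gene of the choroid plexus, was at 384.3 TPM in GFP-TC 1 and 110.7 TPM in ThTC 3 but at 0.18 TPM in sECM only 2. The haemoglobin gene Hbb-bs ran from 36.6 TPM in GFP-TC 3 to 301.0 TPM in GFP-TC 1.

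Over the 9 libraries the T cell score was related to the scores of 3 other immune lists. Pearson's r was 0.89 with GBP and IRG genes (exact permutation p = 0.00163, adjusted 0.00342; Spearman's rho 0.83, exact p = 0.00827, adjusted 0.0331), 0.91 with MHC class I (exact p = 0.00171, adjusted 0.00342; rho 0.77, exact p = 0.0214, adjusted 0.0428) and 0.79 with type I interferon genes (exact p = 0.0126, adjusted 0.0168; rho 0.63, exact p = 0.076, adjusted 0.101). With neurons it was 0.63 (exact p = 0.069, adjusted 0.069; rho 0.53, exact p = 0.148, adjusted 0.148). These were the 4 relations computed. Without GFP-TC 1 and sECM only 2, the 2 libraries farthest from the median T cell score, r was 0.53, 0.49, 0.16 and 0.33 in the same order of GBP, MHC class I, interferon and neurons, so the relations rested largely on those libraries. These p-values treat all 9 libraries as exchangeable, without regard to groups or pairs. Among deviations from the group means r was 0.87, 0.87, 0.73 and 0.71, with exact permutation p = 0.0833, 0.111, 0.167 and 0.0278 over the 36 arrangements within groups that keep the pairs together, not adjusted. The last, for neurons, is the smallest value that 36 arrangements allow. The 3 immune relations did not come under 0.05 in that test.

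The first pattern weighed is the set of 16 lists called higher in ThTC than in GFP-TC. Brain tissue in the samples is argued against only as the whole cause of the size of these differences. With it as a covariate the median of the lists' medians was 0.35, against 0.38 without. The mean neuron and oligodendrocyte scores of the groups differed by 0.14 and 0.10, so the covariate had little group difference to remove. All 16 lists stayed called. That cannot decide, since the same preset list test called lists in all 100 simulated unchanged sets. Whether a low immune content of the library GFP-TC 1 explains most of the size stays open. Without it that median was 0.034 (0.36 to 0.66 without any other of the 6 libraries), and without GFP-TC 1 and its pair ThTC 1 it was 0.17. The pair was left out only after the result without GFP-TC 1 alone had been seen. Leaving out ThTC 1 alone raised the median to 0.48, so the value without the pair mixes opposite shifts. Of the 16 scores, 9 were higher in 3 of 3 pairs. That cannot decide, since the lists were called on these same libraries and the pairs were inferred from them. Correlated genes may account for the number of calls, because 22 of 100 simulated unchanged sets had 17 or more, and also 22 of 100 with deviations shared within pairs. An effect of the secreted factors, the difference the design names, stays open as untested beyond these.

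The second pattern is a group of genes lower in both groups with cells than with sECM only. Retnlg was at 8.28 to 23.5 TPM with sECM only and 0.44 to 1.53 TPM with cells, and Ear2, Ccl24, Rnase2a and Retnla also did not overlap, but limma called 0 genes in the added contrast of both cell groups against sECM only (173 at an unadjusted p under 0.05; adjusted p = 0.060 for Retnlg), as in the other added contrasts tried, ThTC or GFP-TC against both others (2048 and 844). Fewer neutrophils were examined through the other markers of the neutrophil list: 9 of 16 passed the filter, and 8 of these had higher means with cells. Their median log2 fold change was 0.40, and a median above 0 had been set as the result against this cause. Lcn2, the most abundant, was at 41.3, 70.9 and 54.3 TPM with sECM only, GFP-TC and ThTC, but Mmp9 at 18.7, 18.3 and 13.03 TPM. S100a8 and S100a9 averaged 0.45 and 0.33 TPM with sECM only, so they passed the filter mainly through libraries with cells. The median alone cannot decide, since such a filter favours markers that are higher with cells. Lcn2, Mmp9, Csf3r, Il1r2 and Clec4d averaged 2.6 TPM or more with sECM only, so they passed without the libraries with cells. Their log2 fold changes with cells were 0.40, -0.25, 0.057, 0.23 and 0.66. The pattern's genes named above changed by -3.48 (Ccl24) to -2.26 (Retnla). These values argue against fewer neutrophils as the cause, as far as these markers come from neutrophils, which was not tested. Fewer alternatively activated macrophages stay open: 17 of 23 markers that no other list holds passed the filter and went both ways, with a median of -0.0048, at the 7.1 percentile of 10000 random lists matched on expression, with Atp6v0d2 at 2.66, 0.25 and 0.67 TPM in the same order but Ch25h at 26.3, 45.5 and 50.7 and Tgm2, the most abundant, at 148.0, 134.2 and 197.0 TPM. Fewer eosinophils stay open: their median of -0.095 lay at the 2.61 percentile, which had been named beforehand as fitting, but 4 of 14 markers passed the filter, under the 5 required of a list, a limit applied here after the result was seen (Cd24a, the most abundant, at 13.7, 14.1 and 16.2 TPM).

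The third pattern is the predominance of lower genes in ThTC against GFP-TC, 86.4% of those at an unadjusted p under 0.05. It held for small changes only: with a minimum fold of 2, 14 of 43 genes were lower (32.6%) and 29 higher. With the replicate block in the 6 libraries the lower share was 66.4%. Scaling to a fixed total is a candidate explanation that stays open: with median-of-ratios factors the predominance was gone, at 515 lower and 774 higher genes (721 and 663 with quantile scaling) and a lower share of 50.2% among genes without overlap, but that scaling centres the genes, so these shares cannot decide. Whether a few abundant genes caused it stays open: without the 100 most abundant genes the lower share was 76.1%. No biological explanation was tested.

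With 6 libraries there are 10 splits, too few for a share under 0.05. For ThTC against GFP-TC, genes at an unadjusted p under 0.05 numbered 2065 and at most 4856 in another split, with 3 splits as large, and lists 17 and at most 21, with 4 as large. For ThTC against sECM only the counts were 954 and at most 1007 (2 as large), and 14 and at most 17 lists (4 as large). For GFP-TC against sECM only they were 129 and at most 3290 (8 as large), and 11 and at most 23 lists (7 as large). The 0 genes called were matched in all 10 splits of each comparison; the most in another split was 2751 for ThTC against GFP-TC and 0 in the comparisons with sECM only. The split with 2751 calls set GFP-TC 1, ThTC 1 and ThTC 2 against GFP-TC 2, GFP-TC 3 and ThTC 3, which points to a structure of the samples across groups, and the brain-rich libraries stood on one side. Among the 4 splits of ThTC and GFP-TC that part all 3 pairs, which are the real one and 3 that exchange the libraries of 1 number, the real one had the most genes at an unadjusted p under 0.05, 2065 against at most 771, and the most lists, 17 against at most 15. Such a set of 4 splits is also too small for a share under 0.05, and its pairs were inferred from these same libraries. The ranking therefore decides nothing.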
